A study of Homo sapiens with 365 samples.

How the data were processed

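RNA was sequenced from 365 human tumour samples, 1 library per sample, with 17 diagnoses. Of these, 313 came from formalin-fixed, paraffin-embedded (FFPE) blocks and 52 from fresh frozen (FF) tissue. Per the labels, RNA of FFPE sections was made into libraries by hybridization to exome and untranslated-region probes, whereas FF libraries were made from poly-A selected mRNA with a stranded kit. Preservation, extraction kit, library kit and source of the tissue therefore changed together, and no comparison separates them. Immunohistochemistry of the same tumours was not analysed here.

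The deposited values are TPM (abundance scaled to a fixed total per library), which the authors made with kallisto 0.42.4 against GRCh38. The transcript annotation, the summing to genes and any filter applied by the authors are not given in the sources used here. The table held 20062 gene symbols and all 365 samples, and the TPM of every column summed to the same total. It contained 0 mitochondrially encoded genes and 0 replication-dependent histone genes, but 198 immunoglobulin and 202 T cell receptor segments. After 48 Y-linked genes were taken out, 20014 genes were analysed. Of the symbols in the table, 18993 were found in GENCODE release 29, which gave gene identifiers, positions (GRCh38) and transcript lengths. TPM keeps no read counts, so the depth of each library is unknown and no interval for counting error is given.

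Samples were grouped by diagnosis and preservation as labelled. Nothing in the labels says more than that the samples are separate, so p-values measure the spread between samples. No paired analysis was possible because replicate numbers within each group only follow the order of the records and pair no samples between groups.

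Fold changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend, two-sided) on log2(TPM + 1). Folds are taken from these values, so the pseudocount of 1 limits them where a group lies near 0. Mean TPM printed beside a fold is an arithmetic mean, so the ratio of such means can differ widely from the fold. A gene was called where its Benjamini-Hochberg adjusted p over all genes tested was under 0.05 and its absolute log2 fold change was at least 1. Comparisons of diagnoses used FFPE samples alone. One fit held the 9 diagnoses with at least 7 FFPE samples and tested 18950 genes with a TPM of at least 1 in at least 7 samples. In it, breast cancer and neuroendocrine neoplasm were each set against the equally weighted mean of the other 8 diagnoses. Pairs of related diagnoses were compared directly, and pancreatic adenocarcinoma was compared with the equally weighted mean of the colorectal, gastric and esophageal groups. Mean TPM of several diagnoses pools all of their samples, whereas the fitted contrast weights diagnoses equally. Another fit held all 17 diagnoses (19634 genes with a TPM of at least 1 in at least 2 samples), each set against the mean of the other 16. FF and FFPE were compared within breast cancer (18552 genes) and, with diagnosis as a term, in the 7 other diagnoses with at least 3 samples of each kind (18117 genes). The interaction of preservation and diagnosis was tested in 18985 genes.

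Gene lists (45, of which 43 had measured members) and the rule for naming genes were fixed before the data were examined, as were the comparisons, tests, thresholds and most alternatives. The rule named, per comparison, the 10 called genes with the largest and the 10 with the smallest log2 fold change among genes with a mean log2(TPM + 1) of at least 1, besides members of the lists described. It left out immunoglobulin and T cell receptor segments, and this was widened to immunoglobulin heavy constant genes after a list of top genes had been seen. A list score is the mean of log2(TPM + 1) over its measured members. Scores were compared with limma and adjusted over the lists of a comparison, or over all lists and diagnoses for the microenvironment. Some members of the lists and some named genes are not reported here, though counts and scores include them. Counts "adjusted over the list alone" use the list's own members in the adjustment.

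Correlations in breast cancer used Pearson's r and Spearman's rho with two-sided permutation tests (100000 resamples), adjusted over the family. Where a measure was better described by a mixture of 2 normal components (a gain of at least 10 in BIC, a separation of at least 2, at least 6 samples each), r was computed within each component. That rule was written for genes and was also applied to list scores. Components found in the FFPE samples were kept for their alternatives and recomputed for FF.

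The alternatives were a pseudocount of 0.1, no filter on low values, upper-quartile rescaling, quantile normalization, the number of detected genes as covariate, limma without trend, weights by group, a fit of the compared groups alone, FF samples added with preservation as covariate, medians over list members, and leaving out each sample of groups of 2 to 5. Chosen after seeing the data were leaving out 3 libraries that stood apart on principal component 1, leaving out 1 library of each of 3 pairs correlated at a Pearson r over 0.98, and the hepatocyte list score as covariate. Each count was also compared with up to 100 splits of the same samples into groups of the same sizes. The real grouping is counted as 1 of these splits. On simulated data, 100 genes were changed by 1.5 on the log2 scale. In the comparisons of 2 sides, 75% to 100% of them were recovered, with 0 to 8 false calls. The simulated noise was normal and independent between genes, and only well expressed genes were changed. False calls from correlated genes or outlying samples are therefore not covered. Splits of the real samples called up to 144 genes in esophageal against gastric and up to 1263 in FF against FFPE in the 7 other diagnoses. Other tools were the R package data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.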

Results

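Gene expression was measured by RNA sequencing in 365 tumour samples of 17 diagnoses, with 182 FFPE and 19 FF breast cancers as the largest groups. The other FFPE groups were colorectal adenocarcinoma (24), lung adenocarcinoma (19), neuroendocrine neoplasm (13), gastric adenocarcinoma (11), pancreatic adenocarcinoma (10), esophageal adenocarcinoma (9), squamous cell carcinoma other than lung (8), squamous cell carcinoma of lung (7), liver carcinoma with cholangiocarcinoma (5), urothelial cancer (5), prostate adenocarcinoma (4), renal cell carcinoma (4), salivary adenocarcinoma (4), adrenocortical carcinoma (3), high grade serous carcinoma (3) and endometrial carcinoma (2). FF samples also came from lung squamous (7), gastric (6), renal (5), other squamous (5), colorectal (3), liver with cholangiocarcinoma (3), prostate (3) and lung adenocarcinoma (1) tumours. The series title links RNA sequencing with immunohistochemistry (IHC), tumour biomarkers and the microenvironment, and the comparisons follow these themes.

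The read depth of the libraries is unknown, since the values are TPM. FFPE libraries had 15392 ± 428 genes (SD, n = 313) at a TPM of at least 1, against 14098 ± 997 (n = 52) in FF. The upper quartile of TPM was 46.3 ± 4.30 in FFPE and 27.3 ± 6.77 in FF libraries, and the 10 most abundant genes took 5.56 ± 2.26% and 13.3 ± 8.17% of the total. IGKC, the immunoglobulin kappa constant chain, was the most abundant gene in 121 FFPE and 18 FF libraries. The first principal component carried 19.69% of the variance and separated FF from FFPE libraries, with 1 FF library on the FFPE side and 2 FFPE libraries on the FF side.

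**Figure D1:**
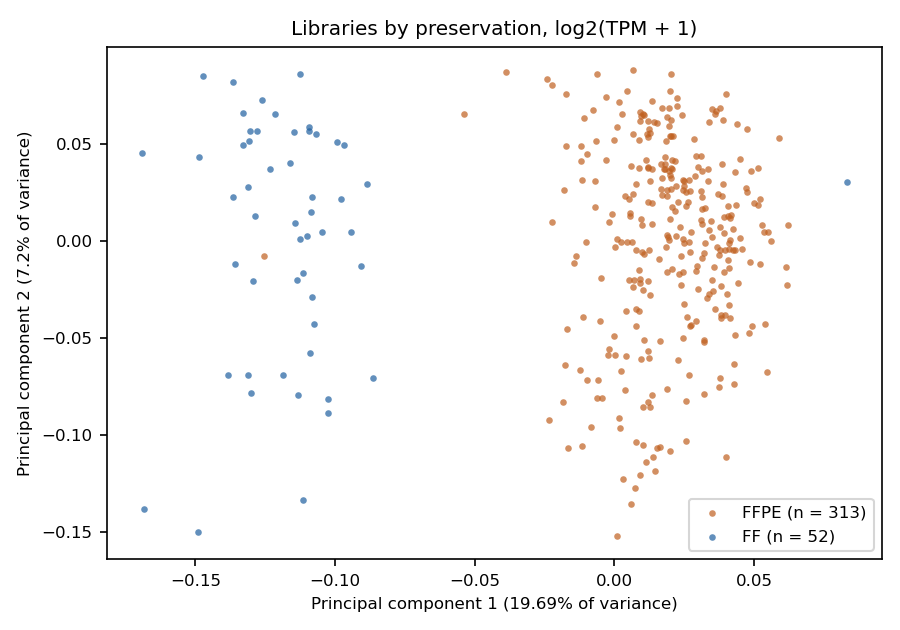
Principal components of log2(TPM + 1), one point per library, with component 1 on the x axis (19.69% of the variance) and component 2 on the y axis (7.20%). FFPE libraries (n = 313) are orange and FF libraries (n = 52) are blue, and 3 libraries lie on the other kind's side of component 1.

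The first question was where the tumour markers commonly stained by IHC were transcribed. In FFPE tissue, KRT20, an intestinal keratin, was 90.3 times the mean of the other 16 diagnoses in colorectal adenocarcinoma (407 ± 327 TPM, SD, n = 24). CDX2, the transcription factor of intestinal identity, was 30.5 times that mean there (log2 fold change 4.93 ± 0.14, SE) and lay above the other samples' median in 24 of 24 samples. ESR1, the estrogen receptor, was higher in breast cancer, at 276 ± 354 TPM (n = 182), with a log2 fold change of 2.60 ± 0.27 (SE, adjusted p = 6.89e-17), and 161 of 182 samples lay above the median of the others. In high grade serous carcinoma (128 ± 74 TPM, n = 3) the ESR1 log2 fold change of 3.03 ± 1.21 did not pass (limma adjusted p = 0.282).

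Of 153 pairs of 9 panel genes and 17 diagnoses, 26 were called. Breast cancer also had more KRT7 (log2 fold change 1.85), a keratin of glandular epithelium, and PGR (1.03), the progesterone receptor, and less KRT20 (-1.42). ERBB2, the HER2 receptor, was 0.78 higher on the log2 scale in breast cancer (adjusted p = 8.65e-08), under the fold change minimum, and was lower in neuroendocrine neoplasm (-1.76, 21.6 ± 10.3 TPM, 13 of 13 samples). Colorectal tumours had less KRT7 (-3.04, 24 of 24 samples). Gastric adenocarcinoma had more KRT20 (4.32 ± 0.46, 10 of 11 samples) and CDX2 (1.18), and esophageal adenocarcinoma more KRT20 (1.96), seen in 5 of 9 samples. KRT7 was higher in pancreatic (2.88, 263 ± 222 TPM) and lung adenocarcinoma (2.47), where KRT20 was lower (-1.36). MKI67, a proliferation antigen, was 240 ± 149 TPM in squamous carcinoma other than lung (n = 8, log2 fold change 1.36). CD274, which encodes PD-L1, was also higher there (1.15, 27.0 ± 21.8 TPM, 7 of 8 samples, adjusted p = 0.0141). Higher means without a call were those of MKI67 in neuroendocrine neoplasm (267 ± 191 TPM, 0.69, limma adjusted p = 0.128) and CD274 in urothelial cancer (30.4 ± 24.7 TPM, 1.34, 0.116). MKI67 was lower in prostate adenocarcinoma (-2.01), and KRT20 was higher in urothelial cancer (2.45, 4 of 5 samples). In adrenocortical carcinoma (n = 3) PGR was higher (3.74, 62.2 ± 12.1 TPM), and ERBB2 (-3.12), MKI67 (-2.03), CD274 (-1.56) and KRT7 (-4.08) were lower.

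Several of these calls were lost in fits with fewer libraries, often with a fold change of about the same size. Without any 1 of the 3 adrenocortical libraries, PGR there kept a log2 fold change of 3.59 to 3.83 but not its call (adjusted p 0.0817 to 0.0916), and MKI67 ranged from -2.35 to -1.49 (0.0680 to 0.252). Without replicate 1 or 2, KRT7 stayed at -4.20 to -3.93 (0.0597 to 0.0799) and CD274 at -1.47 to -1.21 (0.146 to 0.270). A pair of the 3 adrenocortical libraries correlated at an r of 0.984, and whether they are separate tumours is not given in the sources used here. With 1 library of each close pair left out, adrenocortical PGR (3.84, adjusted p = 0.0781), MKI67 (-2.35, 0.0688), CD274 (-1.47, 0.148) and KRT7 (-3.93, 0.0807) were about as large but not called. CD274 there was also not called after quantile normalization (-1.13, 0.115). The prostate call of MKI67 ended without replicate 1, 3 or 4 (-2.03 to -1.46, adjusted p 0.103 to 0.284). PGR in breast cancer fell under the fold change minimum (0.86 to 0.99) without endometrial replicate 1 or high grade serous replicate 2 or 3, and with FF samples added (0.96). KRT20 in esophageal adenocarcinoma was not called with a pseudocount of 0.1 (2.03, adjusted p = 0.127).

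KRT20 in urothelial cancer lost its call in 10 fits that each left out 1 library. The log2 fold change fell without urothelial replicate 1 (1.79, adjusted p = 0.202), 5 (1.55, 0.363) and, less, 4 (2.22, 0.132). It stayed at 2.43 to 2.47, with an adjusted p just over the threshold (0.0505 to 0.0536), without renal replicate 3 or 4, either endometrial library, adrenocortical replicate 2, high grade serous replicate 1 or liver replicate 2. KRT20 was also not called with 1 library of each close pair left out (2.45, 0.0537), with a pseudocount of 0.1 (3.16, 0.0971) or with FF samples added (2.42, 0.0988).

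On GRCh38 the panel genes described here lie at these places in GENCODE 29. ESR1 is on chromosome 6 from 151656691 to 152129619 (plus strand) and PGR on chromosome 11 from 101029624 to 101130524 (minus). ERBB2 spans 39687914 to 39730426 (plus) and KRT20 spans 40875941 to 40885227 (minus) of chromosome 17. MKI67 is on chromosome 10 from 128096659 to 128126385 (minus) and CD274 on chromosome 9 from 5450503 to 5470566 (plus). CDX2 lies on chromosome 13 from 27962137 to 27971139 (minus) and KRT7 on chromosome 12 from 52232520 to 52252186 (plus).

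**Figure D2:**
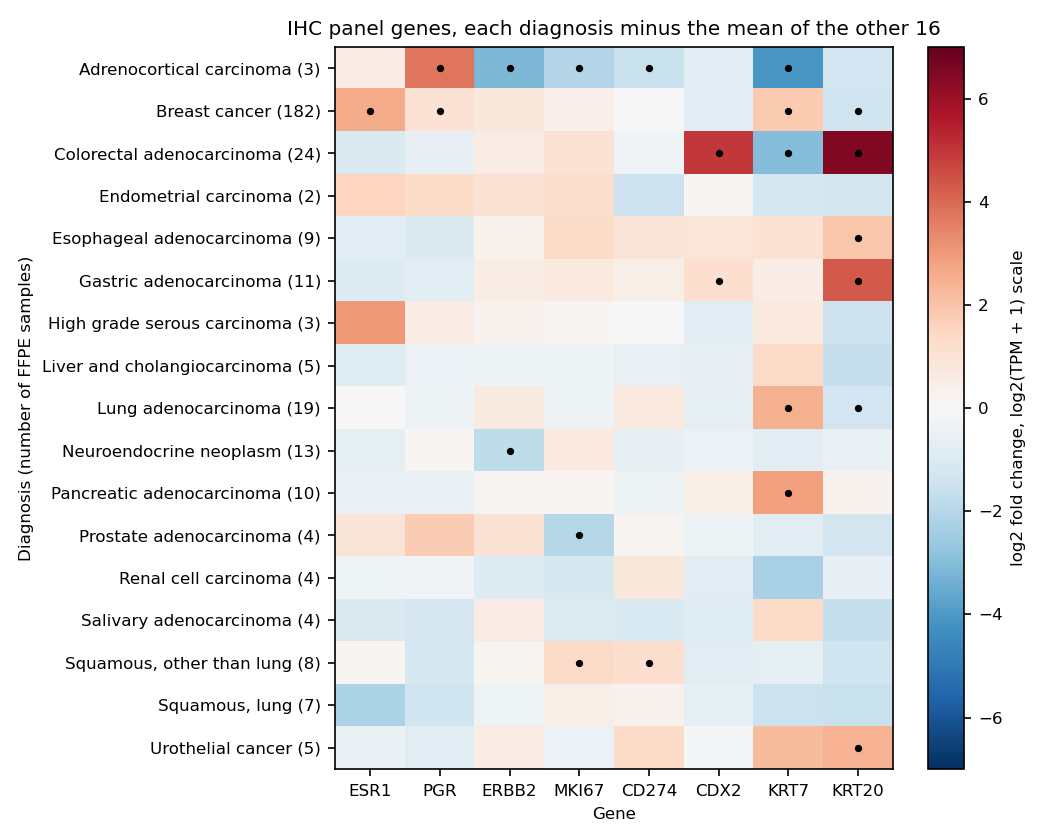
Log2 fold change of 8 IHC panel genes (columns) in FFPE samples of each of 17 diagnoses (lines of the heat map) against the mean of the other 16, with a dot where the gene was called. Colorectal adenocarcinoma has the highest KRT20 (6.50) and CDX2 (4.93) values.

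Tissue lists fixed beforehand were higher in the tumours of their organ in most diagnoses. All 8 adrenal steroid genes were higher in adrenocortical carcinoma than in the mean of the other 16 diagnoses, with a median log2 fold change of 8.47, among them CYP17A1 (10.7 ± 0.50, SE, n = 3) and STAR, which moves cholesterol into mitochondria (9.70 ± 0.58). In prostate adenocarcinoma 8 of 8 prostate genes were higher (median 6.84), including KLK3, the prostate-specific antigen, at 4110 ± 2540 TPM (SD, n = 4). All 8 intestinal genes were higher in colorectal adenocarcinoma (median 4.98), all 8 gastric genes in gastric adenocarcinoma (4.71) and all 8 alveolar genes in lung adenocarcinoma (5.10). Gastric genes were also higher in esophageal (7 of 8) and pancreatic adenocarcinoma (6 of 8), and 7 of 8 intestinal genes were higher in gastric adenocarcinoma. Squamous genes were higher in both squamous groups (10 of 10 each) and in salivary adenocarcinoma (5 of 10). Renal cell carcinoma had 7 of 8 kidney genes higher (median 4.10), among them LRP2, the endocytic receptor megalin (6.79 ± 1.04, n = 4). High grade serous carcinoma had 5 of 7 Müllerian genes higher, including PAX8 (4.66 ± 0.71, n = 3), against 1 of 7 in endometrial carcinoma and 3 of 7 in lung adenocarcinoma. Urothelial cancer had 4 of 7 urothelial genes higher, including UPK1A, a uroplakin (3.58 ± 0.41, n = 5). In liver carcinoma with cholangiocarcinoma (n = 5), which pools tumours of different cell types, 2 of 8 hepatocyte genes were higher (median 4.74). In pancreatic adenocarcinoma (n = 10) 8 of 8 were (4.81). The medians were close, and the difference between these counts was not tested.

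Breast cancer was then compared with 8 other diagnoses. GATA3, a transcription factor of luminal breast cells, was 342 ± 360 TPM (SD, n = 182) in breast cancer and 9.27 ± 18.4 (n = 101) in the others, a log2 fold change of 4.59 ± 0.25 (SE, adjusted p = 6.5e-46, 180 of 182 samples). TRPS1, a GATA-type repressor, reached 2170 ± 1420 against 142 ± 116 TPM (log2 fold change 3.83 ± 0.14, SE, adjusted p = 8.27e-74), above the others' median in 179 of 182 samples. SCGB2A2, which encodes mammaglobin, showed the largest increase at 24.7 times (4.62 ± 0.47), with 154 of 182 samples above that median. CEACAM5, the carcinoembryonic antigen, was 22.2 times lower (49.7 ± 169 against 1210 ± 1570 TPM, 177 of 182 samples).

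Other genes highest in breast cancer were ANKRD30A, a breast differentiation antigen (log2 fold change 4.30), PRLR, the prolactin receptor (3.94), AZGP1 (3.94), EFHD1 (3.72), VTCN1, an immune checkpoint ligand (3.60), PIP, the prolactin-induced protein (3.38), and AARD (3.33). Lower genes included the mucins MUC13 (-3.96), MUC4 (-3.79) and MUC5AC (-3.64), the mucin glycosyltransferase GCNT3 (-3.49) and TSPAN8 (-3.48). The protease TMPRSS4 (-4.04), the transcription factor FOXQ1 (-3.55), the siderophore-binding protein LCN2 (-3.40) and the trypsin inhibitor SPINK1 (-3.37) were lower too. Of 10 breast luminal genes, 9 were higher and TFF1 did not pass (-0.18), with the same 9 adjusted over the list alone and a score difference of 2.77 ± 0.24. Intestinal genes (0 higher, 7 lower of 8) and gastric genes (0 higher, 6 lower of 8) were lower. Of 10 squamous genes 6 were lower, such as KRT6A (-2.98) and SOX2 (-2.16), while KRT5 (-0.17) and KRT14 (0.48) did not pass. Of 7 adipocyte genes 4 were higher, among them PLIN1, which coats lipid droplets (2.56), FABP4 (1.73) and ADIPOQ (1.68). Neutrophil genes (0 higher, 2 lower of 7, such as S100A12 at -1.43) and hypoxia genes (0 higher, 2 lower of 8, ADM at -1.41 and CA9 at -1.40) were partly lower. For each of these lists, the counts adjusted over the list alone were the same.

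Across the 18950 genes tested, 361 were higher and 534 lower in breast cancer. A pseudocount of 0.1 raised the total from 895 to 1614.

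Neuroendocrine neoplasm was compared with 8 other diagnoses. KIF1A, a kinesin that carries synaptic vesicle precursors, was 77.7 times as high (345 ± 290 TPM, SD, n = 13, against 16.5 ± 40.9, n = 270), in 13 of 13 samples and with an adjusted p of 1.36e-19. CHGB, the granule protein chromogranin B, was 69.2 times as high (log2 fold change 6.11 ± 0.41, SE, 12 of 13 samples). All 10 neuroendocrine list genes were higher, 10 also when adjusted over the list alone, among them INSM1 (6.02), SYT4 (5.55), CHGA (5.39) and SYP (4.42), and the list score rose by 5.15 ± 0.20. KRT19, a keratin of simple epithelium, was 10.2 times lower (133 ± 130 against 1040 ± 779 TPM, 13 of 13 samples).

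STXBP5L (6.07), BEX1 (6.02), the zinc finger gene ST18 (5.88, adjusted p = 3.61e-74), NOL4 (5.66), CPLX2, which clamps vesicle fusion (5.51), the glutamate receptor GRIA2 (5.44) and RIMS2 (5.42) were among the 10 largest increases on the log2 scale. Among the largest decreases were GPRC5A (-4.65), CEACAM6 (-4.32), S100A14 (-3.97), LCN2 (-3.94), the integrin ITGB4 (-3.31), C19orf33 (-3.29), the chemokine CCL20 (-3.28) and LIPH (-3.22). Of 7 brain genes 3 were higher, with SNAP25, a SNARE protein, at 4.89 and SYN1 at 2.54. Of 15 microenvironment lists 10 scored lower, also under both rescalings, while B cell (-0.45), endothelium (-0.22) and smooth muscle and pericyte scores (-0.41) did not pass. Neutrophil (-0.68) and checkpoint scores (-0.62) passed when adjusted over the lists of this comparison (adjusted p = 0.0329 and 0.0199) but not over all lists and diagnoses (0.0671 and 0.0521). Plasma cell genes (0 higher, 6 lower of 8) included JCHAIN, the joining chain of antibodies (-2.96), and fibroblast and matrix genes (0 higher, 7 lower of 10, 8 adjusted over the list alone) included LUM (-1.81) and DCN (-1.71). T cell genes (0 higher, 4 lower of 8) included CD2 (-1.58) and CD3E (-1.46). MHC class I (TAP1 at -1.18 and PSMB9 at -1.01) and class II genes (HLA-DRB1 at -1.34 and HLA-DMA at -1.14) each had 2 of 8 lower. No proliferation gene of 10 was called in limma, over all genes or adjusted over the list alone.

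In all, 2162 genes were higher and 1192 lower (64.5% higher), and this split depended on scaling, with 52.1% higher after upper-quartile rescaling and 46.9% after quantile normalization. The median log2 fold change of all genes was 0.17, 0.03 and -0.01 in the same order.

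Lung adenocarcinoma and squamous cell carcinoma of lung differ in histology within one organ. KRT5, a basal keratin, was 672 times lower in adenocarcinoma (10.5 ± 12 TPM, SD, n = 19) than in squamous carcinoma (5980 ± 2920, n = 7), below the squamous median in 19 of 19 samples and with an adjusted p of 1.95e-07. TP63, the transcription factor of squamous epithelium, was 80.1 times lower (log2 fold change -6.32 ± 0.71, SE, adjusted p = 9.09e-14). SFTA2, a surfactant-associated gene, was 41.6 times higher in adenocarcinoma (227 ± 286 against 2.88 ± 4.49 TPM, 18 of 19 samples), and NAPSA, an aspartic protease of alveolar type II cells, was 22.0 times higher.

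All 8 alveolar genes were higher, 8 adjusted over the list alone, including NKX2-1, the lung lineage factor (3.37), SFTPB (4.89), SFTPA2 (4.28), SLC34A2 (4.18), SFTPA1 (4.04) and SFTPC (3.59). CAPN8 (4.15), the melanosome transport gene MLPH (3.77), KRT7 (3.75) and the gluconeogenic enzyme FBP1 (3.65) were higher too. All 10 squamous genes were lower, 10 adjusted over the list alone (score -5.96 ± 0.73), and the largest decreases were in keratins KRT6A (-7.21), KRT17 (-6.19) and KRT13 (-5.82), cornified envelope genes SPRR1A (-6.49) and SPRR3 (-6.18), desmosomal cadherins DSC3 (-6.40) and DSG3 (-5.82), and CLCA2 (-5.81). One squamous library was far below the other 6 for KRT5, KRT6A and CLCA2. MHC class II genes were higher in adenocarcinoma (8 higher, 0 lower of 8, 8 adjusted over the list alone, score 1.79 ± 0.37, adjusted p = 4.17e-05), with HLA-DRB1 at 2.32 and CD74, the invariant chain, at 1.68. Of 8 macrophage genes 3 were higher and 7 adjusted over the list alone, among them MRC1 (2.14), the scavenger receptor MSR1 (1.57) and CSF1R (1.53). Of 8 endothelial genes 3 were higher and 4 adjusted over the list alone (KDR, the VEGF receptor, 1.22; TEK 1.17; CDH5 1.12). No proliferation gene of 10 was called in limma, and 4 were lower adjusted over the list alone.

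The comparison gave 703 genes higher and 552 lower (56.0% higher), against 45.7% higher after upper-quartile rescaling and 41.2% after quantile normalization. With FF samples added and preservation as covariate, 157 genes were higher and 405 lower (562 in all, 27.9% higher), and SFTPB (1.27, adjusted p = 0.390), SFTPA2 (0.71), SFTPA1 (0.70), SLC34A2 (2.39), CAPN8 (2.59), MLPH (2.35) and KRT7 (1.82) no longer passed. In a fit of the 2 groups alone SFTPB, SFTPA1 and SFTPA2 were not called (adjusted p 0.0769 to 0.202).

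Colorectal and gastric adenocarcinomas were compared as tumours of the lower and upper gut. FABP1, the fatty acid binding protein of enterocytes and hepatocytes, was 104 times as high in colorectal tumours (3340 ± 2910 TPM, SD, n = 24) as in gastric tumours (512 ± 901, n = 11). CDX2 was 11.6 times as high (log2 fold change 3.53 ± 0.23, SE). PGC, the gastric proenzyme pepsinogen C, was 42.4 times lower (2.31 ± 4.82 against 658 ± 855 TPM, 24 of 24 samples, adjusted p = 3.64e-11). The gastric surface mucin MUC5AC was 28.6 times lower (31 ± 49.8 against 1470 ± 1840 TPM).

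Intestinal genes were higher in 7 of 8 cases, 7 adjusted over the list alone, with CDX1 at 3.38, GPA33, a surface antigen of intestinal epithelium, at 2.85 and KRT20 at 2.05, while LGALS4 (0.85) did not pass. Further increases were in the mucin MUC12 (4.74, adjusted p = 4.24e-21), NXPE1 (4.65), NXPE4 (4.13), CDHR1 (4.02), the dipeptidase DPEP1 (3.79), the chloride-bicarbonate exchanger SLC26A3 (3.68), CLDN3 (3.67), the NADPH oxidase NOX1 (3.65) and the intestinal cadherin CDH17 (3.52). Gastric genes were lower in 7 of 8 cases and in 8 adjusted over the list alone, among them GKN1 (-5.24), TFF2 (-4.21) and CLDN18 (-3.57), with TFF1 at -3.03 not passing over all genes. DPCR1 (-5.38), ANXA10 (-4.82), PSCA, the prostate stem cell antigen (-4.74), PIK3C2G (-4.40), VSIG1 (-3.92), the protease CTSE (-3.84), SPTSSB (-3.79), the deacetylase AADAC (-3.65) and KRT7 (-3.35) were lower as well. Immune lists were lower in part, with 4 of 8 MHC class II genes lower and 7 adjusted over the list alone (score -1.10, adjusted p = 0.00639). For macrophages, 2 of 8 genes were lower and 4 adjusted over the list alone (CD68 at -1.29 and C1QB, a complement component, at -1.28). In all, 260 genes were higher and 132 lower in colorectal tumours.

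Esophageal and gastric adenocarcinomas differed in few genes. SPRR3, a cornified envelope protein of the esophageal lining, was 8.75 times as high in esophageal tumours (1100 ± 3190 TPM, SD, n = 9, against 1.95 ± 2.78, n = 11), above the gastric median in 7 of 9 samples (adjusted p = 0.0163). KRT13, a keratin of that lining, was 7.84 times as high in 5 of 9 samples. LYRM5 was 2.36 times as high (124 ± 87.2 against 43.6 ± 10.5 TPM, 9 of 9 samples), and the endoribonuclease ENDOU 2.45 times (8 of 9 samples).

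These were among 14 genes higher and 0 lower. Others, 9 chosen after their values were seen, were the squamous lining genes KRT4 (2.63), CRNN (1.97) and TMPRSS11B (1.13), the antimicrobial genes REG3A (1.98) and DEFB4B (1.71), NLRP4 (1.46), IL36A (1.21) and 2 immunoglobulin D segments. Of 10 squamous genes none was called and 3 were higher adjusted over the list alone, with KRT5 (3.95) and KRT6A (3.74) not passing over all genes and a score difference of 1.93 (adjusted p = 0.2). Of 8 intestinal genes, 0 were called and 2 were lower adjusted over the list alone. In limma, 357 genes were higher and 150 lower at an unadjusted p under 0.05. Fitting the 2 groups alone gave 0 calls (300 higher and 181 lower at an unadjusted p under 0.05), and with a pseudocount of 0.1 there were 4, without SPRR3, KRT13, ENDOU and LYRM5. LYRM5 also lost its call after upper-quartile rescaling (adjusted p = 0.0608) and after quantile normalization, and of 100 splits of the samples 32 called at least 14 genes, up to 144.

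Pancreatic adenocarcinoma was compared with the 3 other digestive adenocarcinomas. On the log2(TPM + 1) scale ALB, the serum albumin made by hepatocytes, was 89.6 times as high in pancreatic tumours (n = 10) as in the others (n = 44). It lay above their median in 9 of 10 samples (limma adjusted p = 0.000523). Its arithmetic means were 3000 ± 3510 (SD) and 375 ± 1540 TPM. All 8 hepatocyte genes were higher, 8 adjusted over the list alone, with a score difference of 4.71 ± 1.07 (SE). Pancreatic enzymes were higher in 6 of 7 cases and in 7 adjusted over the list alone, among them the trypsinogen PRSS1 (log2 fold change 3.91), CLPS (3.90), CTRB1 (3.63) and CPA1 (3.56), with CEL at 1.62 not passing over all genes.

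The other largest increases were liver-secreted proteins, namely C-reactive protein (CRP, 70.5 times), the vitamin D binding protein GC (62.1 times), the fibrinogen chains FGB (57.4), FGG (56.9) and FGA (54.5), APOB (43.8), ORM1 (42.3), AMBP (40.7) and APCS (37.6), each in 9 of 10 samples. The hepatocyte score was 8.09 ± 3.99 (SD, n = 10) in pancreatic, 3.87 ± 2.68 in esophageal, 3.50 ± 2.33 in gastric and 2.78 ± 2.67 in colorectal tumours, and 1 esophageal library was far above the other 8 for ALB, CRP, GC, ORM1, AMBP and APCS. Intestinal genes were lower in 5 of 8 cases and in 6 adjusted over the list alone, including KRT20 (-3.77, 9 of 10 samples) and CDX1 (-2.98, 10 of 10 samples, adjusted p = 3.91e-18). PHGR1 (-3.88), IRX2 (-2.92), the goblet cell gene SPINK4 (-2.85), CDH17 (-2.83), NXPE1 (-2.63), the transcription factor MYB (-2.58), the deiodinase DIO2 (-2.48, 7 of 10 samples) and the sodium-proton exchanger SLC9A3 (-2.46) were also lower. One interferon gamma response gene of 9, IDO1, which degrades tryptophan, was lower (-2.13), and 6 were lower adjusted over the list alone (score -1.22, adjusted p = 0.0384).

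In all, 428 genes were higher and 125 lower. With the hepatocyte score as covariate, an alternative chosen after seeing the data, 111 were higher and 89 lower, and 93 of the 428 and 68 of the 125 were still called, without ALB, FGB, FGG, FGA, APOB, ORM1, APCS and DIO2.

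**Figure D3:**
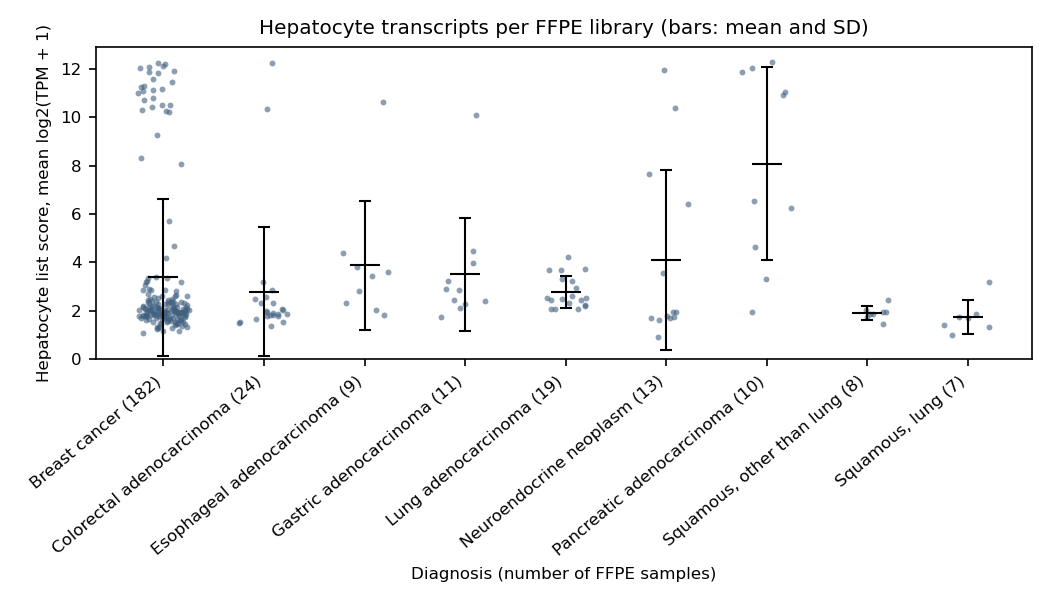
Hepatocyte list score (mean log2(TPM + 1) of 8 genes, y axis) of each FFPE library in 9 diagnoses (x axis), with bars for the mean and SD. Pancreatic adenocarcinoma averages 8.09 ± 3.99 (n = 10), and the other 8 groups average from 1.74 to 4.09.

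Squamous carcinomas of lung (n = 7) and of other sites (n = 8) were compared as tumours of one cell type. MGST1, a microsomal glutathione transferase, was 13.1 times as high in lung (836 ± 419 against 111 ± 125 TPM, SD, 7 of 7 samples, adjusted p = 0.00764). GLI2, an effector of hedgehog signalling, was 9.70 times as high (log2 fold change 3.28 ± 0.54, SE, 6 of 7 samples, adjusted p = 8.82e-06). EPCAM, an epithelial adhesion molecule, was 324 ± 179 against 59.8 ± 57.8 TPM. CCL20, a chemokine that attracts CCR6-bearing cells, was 10.9 times lower in lung on the log2(TPM + 1) scale, in 6 of 7 samples. Its arithmetic means were 47.1 ± 81.9 against 169 ± 120 TPM. MMP28, a matrix metalloproteinase, was 10.5 times lower in lung.

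Detoxifying enzymes AKR1C3 (3.08) and UGT1A7 (2.99) were higher, as were FREM2 (3.53), ATP13A5 (3.50), the transcription factor DMRT2 (3.02), the glypican GPC3 (2.97) and the fibrillin FBN2 (2.73). PLCH2 (-2.77), the cytokine receptor subunit IL20RB (-2.58), the glutamate receptor GRIN2A (-2.43), NIPAL4 (-2.29), SH3TC1 (-2.25), INPP1 (-2.20) and the antiviral gene OAS3 (-2.15) were lower. Of 10 squamous genes none was called over all genes and 1 was higher adjusted over the list alone. No member of the MHC class I, MHC class II or immediate early lists was called over all genes, but 6 of 8, 5 of 8 and 8 of 10 were lower adjusted over the list alone, with scores of -1.06, -1.13 and -1.48 (each adjusted p = 0.103). In limma, 747 genes were higher and 1368 lower at an unadjusted p under 0.05.

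In all, 57 genes were higher and 55 lower in lung (50.9% higher), against 68.5% higher after upper-quartile rescaling and 66.7% after quantile normalization. With FF samples added, 77 were higher and 20 lower (79.4% higher), and 40 calls were shared in direction with the 112. A limma fit of these 15 samples alone called 0 genes (533 higher and 1095 lower at an unadjusted p under 0.05, smallest adjusted p 0.0561). In the fit with FF samples added, CCL20, PLCH2, GRIN2A, NIPAL4, SH3TC1 and FBN2 were not called, and with a pseudocount of 0.1 neither were CCL20, UGT1A7, GPC3, FBN2 and IL20RB.

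Microenvironment lists were compared over 9 FFPE diagnoses, and 14 of 15 scores differed by limma's moderated F, all except B cells (adjusted p = 0.117). Smooth muscle and pericyte genes (F = 8.10, adjusted p = 1.06e-08) and MHC class II genes (F = 7.49, adjusted p = 3.29e-08) differed most. Neuroendocrine neoplasm scored below the mean of the other 8 diagnoses in 10 lists, with plasma cells at -1.47 ± 0.34 (SE, n = 13), fibroblasts and matrix at -1.17 ± 0.37, T cells at -1.06 ± 0.30, regulatory T cells at -1.03, interferon gamma response at -1.0, MHC class II at -0.95, MHC class I at -0.78, CD8 and cytotoxic cells at -0.77, macrophages at -0.73 and dendritic cells at -0.67. Lung adenocarcinoma scored higher for MHC class II (1.00 ± 0.21, n = 19), macrophages (0.75) and dendritic cells (0.51). Gastric adenocarcinoma scored higher for MHC class II (0.77) and class I (0.70), and squamous carcinoma of lung lower for MHC class II (-1.01 ± 0.33, n = 7). Colorectal adenocarcinoma had the highest smooth muscle and pericyte score (1.16 ± 0.23 above the others, n = 24), and esophageal adenocarcinoma scored higher for endothelium (0.68 ± 0.25, n = 9). Breast cancer scored lower for neutrophils (-0.80 ± 0.13, n = 182), smooth muscle and pericytes (-0.54) and MHC class I (-0.27). Checkpoint genes differed by the F test (adjusted p = 0.00400) without any single diagnosis passing. Of all these differences, 21 passed.

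**Figure D4:**
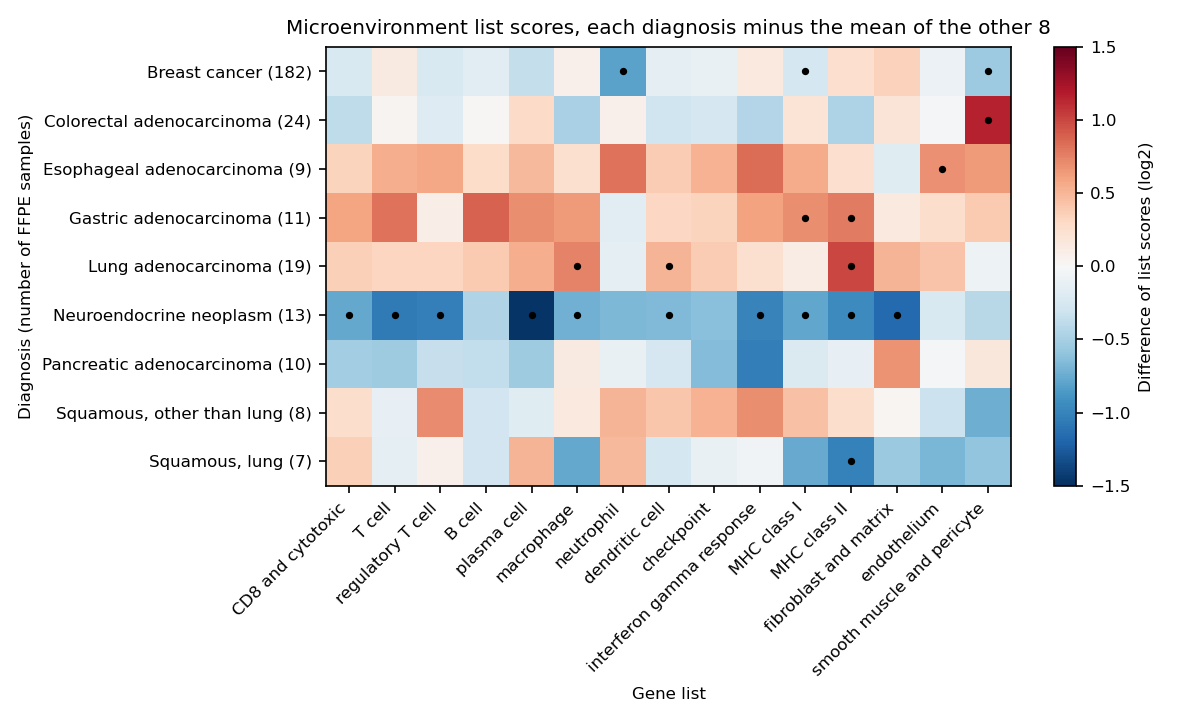
Difference of 15 microenvironment list scores (log2 scale, columns) in 9 FFPE diagnoses from the mean of the other 8, with a dot at an adjusted p under 0.05. Neuroendocrine neoplasm is below the others with a dot in 10 lists, down to -1.47 for plasma cells.

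Within FFPE breast cancer (n = 182), CD274 was correlated with 5 of the 8 measures set against it. Its Pearson r was 0.79 with PDCD1LG2, which encodes PD-L2 (Spearman rho 0.80), 0.74 with the interferon gamma response score (rho 0.70), 0.61 with CD8A (rho 0.61), 0.59 with MHC class I genes (rho 0.58) and 0.39 with macrophage genes (rho 0.40). Permutation p-values for these pairs were 1e-05, the smallest that the resamples can give (adjusted 2.9e-05 for r and 3.63e-05 for rho). Without the 2 samples farthest from the median of CD274, r was 0.78, 0.71, 0.60, 0.56 and 0.37 in the same order. CD274 was not correlated with fibroblast (r = 0.08), endothelial (0.11) or MKI67 (0.06) values, nor CD8A with fibroblast genes (0.10), at an adjusted p under 0.05. MKI67 followed the proliferation score (r = 0.88, rho 0.85), and ERBB2 followed its chromosomal neighbour GRB7 (r = 0.74, rho 0.60, and 0.68 without the 2 farthest samples).

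ESR1 was split into 2 components, so correlations were computed within the lower (n = 83) and the higher (n = 99). ESR1 correlated with PGR in both (r = 0.40 and 0.27, rho 0.32 and 0.26), with GATA3 in the higher (0.47, rho 0.38; 0.16 in the lower) and inversely with MKI67 in the lower (-0.36, rho -0.36; 0.05 in the higher). The difference between components was not tested. CD8A followed B cell genes in the lower B cell component (r = 0.45, n = 137) but not in the higher (0.18, n = 45). ERBB2 with ESR1, and ESR1 with basal epithelial genes, did not pass in any component of the FFPE samples. Of 29 correlations, 15 passed for r. In FF breast cancer (n = 19), the other batch, no measure was split, so values there span all samples and differ in kind from those within components. Of 20 pairs 9 passed, among them CD274 with PDCD1LG2 (r = 0.67) and interferon gamma response (0.58), MKI67 with proliferation (0.90), ERBB2 with GRB7 (0.84), ESR1 with GATA3 (0.81) and ESR1 with basal epithelial genes (-0.68, rho -0.66, adjusted p = 0.00531). ERBB2 with ESR1 passed there for rho (0.58, adjusted p = 0.0242) but not for r (0.38). CD274 with CD8A had r = 0.45 there (adjusted p = 0.0903) and a rho of 0.55 (adjusted p = 0.0289).

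FF and FFPE tissue were compared within breast cancer (n = 19 and 182), a comparison in which the library kit and the source changed with preservation. RPL13A, a protein of the large ribosomal subunit, was 102 times as high in FF (2400 ± 928 TPM, SD, against 50.6 ± 366), and RPS27, of the small subunit, was 6710 ± 2080 against 204 ± 626 TPM. MALAT1, a nuclear long noncoding RNA, was lower in FF by 600 times, a fold limited by the pseudocount of 1 (0.0028 ± 0.0122 against 709 ± 385 TPM, 19 of 19 samples, adjusted p = 3.49e-92). RPL9 (log2 fold change 6.41), RPS12 (5.78), RPLP1 (4.95), RPS28 (4.85), the nucleosome-binding proteins HMGN1 (5.48) and HMGN2 (4.89), UBE2V1 (5.13) and TMA7 (4.74) were also higher in 19 of 19 samples. TMEM14E (-7.08), SPDYE16 (-5.88), the zinc finger gene ZNF460 (-5.62), PRSS48 (-5.37), NPIPB11 (-5.21), ARHGAP11B (-5.19) and 3 genes named by clones, 1 of them listed at 0 in all 19 FF samples, were lower.

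Across 18552 genes, 1329 were higher and 6627 lower in FF (16.7% higher). The median log2 fold change of all genes was -0.55, against -0.12 after upper-quartile rescaling (45.9% higher) and -0.01 after quantile normalization (50.1% higher). Of 43 list scores, 22 differed. Cytosolic ribosomal protein genes were higher (6 higher, 0 lower of 10, 6 adjusted over the list alone, score 2.36 ± 0.13, SE), as were HER2 amplicon genes (4 of 5, such as MIEN1 at 2.52, while ERBB2 itself at 0.32 did not pass) and nuclear oxidative phosphorylation genes (score 0.54). Of 8 MHC class I genes 4 were higher (B2M 2.34, HLA-C 2.06 and HLA-B 1.29 among them) and NLRC5, their transactivator, was lower (-1.42). Lower lists were T cells (0 higher, 7 lower of 8, score -1.45 ± 0.25), regulatory T cells (1 higher, TNFRSF18, and 5 lower of 6, -1.53), checkpoint genes (0 higher, 5 lower of 8, such as CD274 at -2.14 and CTLA4 at -2.17), interferon gamma response (0 higher, 6 lower of 9, such as GBP5 at -2.57), proliferation (0 higher, 6 lower of 10, MKI67 at -3.63) and adipocytes (0 higher, 4 lower of 7). Adjusted over the list alone, these counts were the same. After both rescalings, ribosomal, amplicon and MHC class I scores stayed higher and T cell (-0.93 and -0.61), checkpoint and interferon scores lower, while proliferation no longer passed after quantile normalization (-0.54, adjusted p = 0.0513) and adipocytes after either (-0.45 and -0.27). The CD8 and cytotoxic score did not pass (-0.26) and changed sign with scaling (0.35 and 0.63). Among the IHC markers, KRT7 was higher in FF (1.12), and ESR1 (-1.82) and PGR (-1.85) were lower.

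In 7 other diagnoses (32 FF and 63 FFPE samples), 1270 genes were higher and 5894 lower in FF (17.7% higher), against 52.6% higher after upper-quartile rescaling and 48.7% after quantile normalization. The median log2 fold change of all genes was -0.45, 0.01 and -0.01 in the same order. RPL13A was 75 times as high, with RPL9 at 5.78 and RPS12 at 5.45 on the log2 scale, and MALAT1 was 473 times lower (2.07 ± 11.7 against 639 ± 343 TPM, 32 of 32 samples), with TMEM14E at -6.78, ZNF460 at -5.13 and NPIPB11 at -4.66. Ribosomal (2.16), HER2 amplicon (1.12) and MHC class I scores (0.70) were higher, and proliferation was lower (-1.30, MKI67 at -3.37), in each case under both rescalings too. CD8 and cytotoxic genes scored 1.02 higher (2 of 8 genes, NKG7 at 2.15 and GNLY at 1.77), and the T cell score did not pass (-0.17) and changed sign with scaling (0.44 and 0.47). Fold changes of 17940 genes in breast cancer and in the 7 other diagnoses, which share no samples, had an r of 0.909 across genes, which are not independent replicates. Both comparisons called 912 genes higher and 5299 lower, against 93.7 and 2174 by chance overlap, and 18 in opposite directions.

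**Figure D5:**
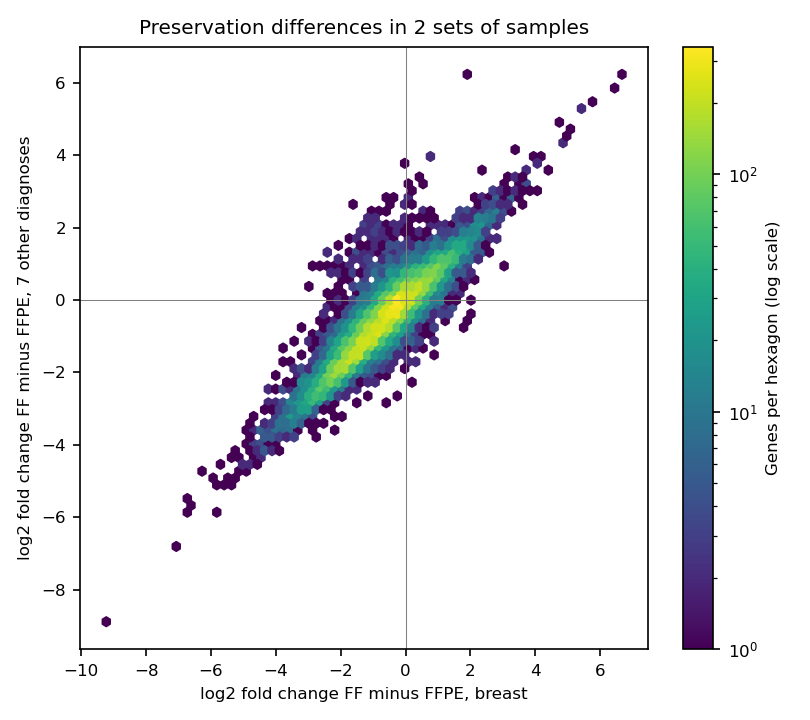
Log2 fold change of FF against FFPE for 17940 genes in breast cancer (x axis) and in 7 other diagnoses (y axis), with shade for the number of genes per hexagon. The values follow one another with an r of 0.909 across genes.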

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

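Tests on transcript length and GC content, on the hepatocyte transcripts, on the variation of the preservation difference between diagnoses, and all splits of the samples were chosen only after results were seen, whereas the tests on histone genes, tissue content and a general property of preservation were written before.

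FF and FFPE breast libraries differed in 7956 genes. Of 100 splits of the samples 1 was as large, the real one, with 13 calls at most in the others. That is the smallest share these splits can give, and it was not adjusted over the comparisons. A general property of preservation and kit fits, since fold changes in 7 other diagnoses had an r of 0.909 with those in breast. Transcript length and GC content stay open: with their trend removed, 56.6% of called genes kept a log2 change of at least 1 in breast, above a bar of 50% set after results were seen, but 47.8% did in the 7 other diagnoses. Loss of RNAs without a poly-A tail could not be tested, because 0 replication histone genes were measured. Different tissue content stays open: the T cell score was 1.45 lower in FF, at -1.45 beyond the size of 1 set beforehand, but it was -0.93 and -0.61 after rescaling and -0.17 in the other diagnoses, and the condition that rescaled values also reach 1 was added after these values were seen.

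Hepatocyte transcripts were higher in pancreatic adenocarcinoma than in 3 digestive adenocarcinomas, with 8 of 8 list genes called. The comparison called 553 genes, and 1 of 100 splits was as large, the real one, with 227 at most in the others. That share was not adjusted over the comparisons. RNA of liver cells in the sampled tissue may be a source: the 8 genes rose and fell together over the 10 pancreatic samples (median pairwise r 0.854, smallest 0.66), ALB averaged 3000 TPM there, and 0 of the 8 genes are held by another list. An acute-phase response of the tumour cells alone is argued against, since ALB, APOA1, APOB, TTR and CYP2E1, which are not induced in it, had a median log2 fold change of 4.42. With the hepatocyte score as covariate 200 genes were called, and the loss of the hepatocyte genes themselves is by construction. Whether the samples came from liver metastases or lay beside liver is not given in the sources used here.

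The FF minus FFPE difference varied with the diagnosis in 3519 of 18985 genes. Of 100 splits, the real one included, 5 were as large, and the highest other called 8591. Each split reassigned FF and FFPE within each diagnosis, which also broke up the difference shared by the diagnoses. The splits therefore cannot judge chance for the interaction, and chance was not excluded. Libraries that stood apart on principal component 1 may account for a part, since 613 genes were left without them. No other libraries were left out for comparison, so their share was not told apart from chance. Normal lung tissue in some lung squamous blocks might add to the variation between diagnoses. The lung alveolar score there was 5.61 higher in FF (7.84 ± 4.11, SD, n = 7) than in FFPE (2.23 ± 1.92, n = 7), and 0 of the 8 alveolar genes are held by another list. Whether any of these blocks held normal lung tissue stays open.

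The interaction of preservation and diagnosis flagged CD274 (adjusted p 0.0237, and 0.307 without the libraries apart) and KRT20 (0.0149, and 0.0532 without them). Of 43 list scores it flagged 17: lung alveolar (6.92e-07), adrenal steroidogenic (1.4e-05), T cell (0.00737), checkpoint (0.00737), heat shock (0.00737), CD8 and cytotoxic (0.00774), B cell (0.00887), immediate early (0.00887), squamous (0.0107), lymph node stroma (0.0107), dendritic cell (0.0135), neuroendocrine (0.0294), endothelium (0.0303), oxidative phosphorylation (0.0408), kidney (0.0423), brain (0.0423) and cytosolic ribosomal protein (0.0486). Without the libraries apart 5 of them passed, namely lung alveolar (6.53e-07) and squamous, CD8 and cytotoxic, immediate early and heat shock (each 0.0486).

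Dixon's ratio was computed for 183 sets, each holding the values of 1 gene in the FFPE samples of 1 diagnosis. A sample far from the others was found in 25 of these sets. Chance alone flags about 1 in 20 sets where values are normal. Some flagged values lay under a TPM of 1, and several genes flagged the same library, so the sets are not independent. The count of 25 can therefore not be judged against that rate. In esophageal adenocarcinoma 1 library was highest for ALB (0.621), AMBP (0.732), APCS (0.822), CRP (0.953), GC (0.64) and ORM1 (0.666), another was highest for ERBB2 (0.615), and IRX2 had a low sample (0.6). In squamous carcinoma of lung, high samples were seen for CD274 (0.717), CDX2 (0.612), GRIN2A (0.705) and KRT7 (0.616), each in another library, and 1 library was lowest for CLCA2 (0.748), KRT5 (0.728) and KRT6A (0.673). Squamous carcinoma of other sites had a high sample for CDX2 (0.868). The highest CDX2 value was 0.662 TPM there and 0.715 TPM in squamous carcinoma of lung, both under a TPM of 1. In pancreatic adenocarcinoma 1 library was lowest for ERBB2 (0.655) and KRT7 (0.608), and 1 was highest for KRT20 (0.56) and SPINK4 (0.672). Liver carcinoma with cholangiocarcinoma had high samples for ESR1 (0.732) and KRT20 (0.932, at only 1.48 TPM) and a low one for KRT7 (0.744). Renal cell carcinoma had a high one for KRT20 (0.834) and a low one for MKI67 (0.86).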

How the results depend on the processing

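The splits and the settings named here as added were chosen only after results were seen. Most values kept their direction and their side of the threshold. For named genes 1669 of 1730 did and for panel genes 925 of 962, with 0 reversed. For list scores 124 of 154 did, with 6 reversed, and for correlations 124 of 127. These totals pool settings that can hardly move a call with settings that can. Of the 962 panel values, 780 left out 1 library of a small group. Fits of the compared groups alone kept 57 of 85 named genes. With 1 library of each close pair left out, 21 of 26 panel calls were kept. Quantile normalization kept 10 of 22 list scores. The number of called genes moved by over 1.5 times in few cases. Breast against 8 diagnoses went from 895 to 1614 with a pseudocount of 0.1, lung adenocarcinoma against lung squamous from 1255 to 562 with FF samples added, and esophageal against gastric from 14 to 4 with that pseudocount; the cause was not tested. Fits of the compared groups alone, which hold fewer samples, called 0 genes in esophageal against gastric and 0 in lung squamous against other squamous (14 and 112 before). With the hepatocyte score as covariate, added, the pancreatic comparison called 200 genes, of which 161 were among its 553 calls without it. A count that stayed similar can hold other genes. In FF against FFPE in breast, upper-quartile rescaling called 7002 genes and quantile normalization 6467. Of the 7956 calls before, 5120 and 4517 were kept in the same direction. In the 7 other diagnoses 4263 and 4203 of 7164 were kept, in the same order. Correlations that passed were 15 of 29 in FFPE and 9 of 20 in FF breast samples, which are fewer. Reversed were scores of FF against FFPE in breast: prostate (0.183 after upper-quartile rescaling and 0.388 after quantile normalization), fibroblast and matrix (0.0355, upper-quartile), intestinal (0.098, quantile) and dendritic cell (0.291, quantile, and 0.194 with detected genes as covariate); the cause was not tested. Leaving out 1 library of a small group gave 22 to 27 panel calls (26 before) and 7082 to 7732 genes in FF against FFPE in the 7 other diagnoses (7164 before). TPM holds no counts, so what depth limits could not be measured.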

Other observations

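All tests of splits given here were chosen only after results were seen. Salivary adenocarcinoma (n = 4, FFPE) had 4 of 8 basal epithelial and 5 of 10 squamous list genes higher. KRT5 and KRT14 belong to both lists, so these counts overlap. Against the mean of the other 16 diagnoses, KRT5 was 69.8 times as high (2110 ± 1010 TPM, SD), KRT14, its partner keratin, 46.4 times (247 ± 187 TPM) and SOX10, a transcription factor of myoepithelial and neural crest cells, 32.7 times (167 ± 97.7 TPM, log2 fold change 5.03 ± 0.95, SE). The desmosomal cadherins DSC3 (5.73) and DSG3 (4.69) were higher as well, and PIP (492 ± 332 TPM) and TRPS1 (2500 ± 165 TPM), both also high in breast cancer, were 32.3 and 15.6 times the mean of the others. The mitotic genes CCNB1 (-1.78) and AURKA (-1.63) were lower. Prostate adenocarcinoma had KLK2 at 792 ± 642 TPM (n = 4, log2 fold change 8.82), and adrenocortical carcinoma had CYP11B1, which completes cortisol synthesis, at 481 ± 169 TPM (n = 3, 8.74).

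The number of genes called against the other 16 diagnoses was largest in adrenocortical carcinoma (1779 higher, 1663 lower) and neuroendocrine neoplasm (1851 and 675), followed by renal cell carcinoma (868 and 398) and salivary adenocarcinoma (673 and 559), and smallest in urothelial cancer (64 and 23). The diagnoses held from 2 to 182 FFPE samples, so these counts were not made at equal group size. After IGKC, the most abundant gene was PABPC1, the poly-A binding protein, in 21 FFPE libraries and MGP, the matrix Gla protein, in 14, and FTH1, ferritin heavy chain, in 4 FF libraries. Among libraries on the other kind's side of component 1, a colorectal FF library had 19509 genes at a TPM of at least 1 and an upper quartile of 57.6. Its gene number and its median TPM of 37.2 were above the FFPE maxima of 16912 and 21.4. It was 1 of the 3 colorectal FF libraries in the comparison of 7 other diagnoses and in the interaction. The FFPE libraries on the FF side were a urothelial (upper quartile 27.6) and a breast library (24.8), against an FFPE mean of 46.3. The urothelial counts above include that urothelial library. In 3 pairs of FFPE libraries Pearson r was over 0.98 (0.992 and 0.986 in breast cancer and 0.984 in adrenocortical carcinoma), and whether these are separate tumours is not given in the sources used here.

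For several comparisons, none of the 100 splits of the samples was as large as the real one except the real one itself. These were breast against 8 diagnoses (895 calls, 1 at most in the others), neuroendocrine against 8 diagnoses (3354, 24), lung adenocarcinoma against lung squamous (1255, 127), colorectal against gastric (392, 46), FF against FFPE in 7 other diagnoses (7164, 1263), microenvironment scores (14, 2), list scores of FF against FFPE in breast (22, 9) and the IHC panel (26, 2). Random groupings thus seldom gave as many calls, but 1 of 100 is the smallest share these splits can give. It was not adjusted over the comparisons. For breast, neuroendocrine, microenvironment scores and the panel, each split reassigned all diagnoses at once. Those splits stand for no difference between any diagnoses. For lung squamous against other squamous 3 splits, the real one included, were as large, a share under 0.05 (112 calls, 139 at most in the others). That share was not adjusted over the comparisons, and a fit of these samples alone called 0 genes, so chance is not excluded. For esophageal against gastric 32 splits, the real one included, were as large, so chance was not excluded. The highest other split called 144 genes against 14, and the median of the others was 6. What made that split so large was not tested.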
